A study of Homo sapiens with 15 samples.

How the data were processed

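Stranded total RNA, depleted of ribosomal RNA, was sequenced from KPL4, a human breast adenocarcinoma cell line with amplified HER2 (ERBB2). The series held 15 libraries in 5 groups of 3. Control cells carried their own estrogen receptor β (ERβ, encoded by ESR2), knockout cells had lost it, and add-back cells were knockout cells into which ERβ had been put back. The last 2 groups were add-back cells kept for 72 h in phenol red-free medium with 1% charcoal-treated serum and then given DMSO (vehicle) or 200 nM LY500307, an ERβ agonist, for 24 h.

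Per the submitters' processing notes the reads passed through FastQC, Trim Galore, GSNAP and RSEM on GRCh38. No versions were given, and neither the annotation release nor the use of strand in counting could be read from the notes. The authors deposited RSEM expected counts per gene and per transcript, not normalised. The gene table had 60664 entries, and expected counts were rounded to whole numbers. Totals ran from 12614074 expected counts (knockout replicate 2) to 19390378 (vehicle replicate 2). Positions, gene types, GC content and transcript length came from GENCODE 29, which had an entry for 58396 of the gene identifiers.

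Genes were tested with edgeR 4.0.16 in R 4.3.3. Low counts were filtered with filterByExpr by group, which left 19516 genes. TMM factors, 1 group-means model of all 15 libraries and the two-sided quasi-likelihood F test followed, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes of a comparison. The biological coefficient of variation was 4.99%. Levels are CPM with TMM scaling, given as mean ± SD over 3 libraries, and log2 fold changes are given ± SE of the fit. The p-values measure the spread between libraries of a group, and the labels do not state whether these came from separate cultures. Squared differences between the counts of pairs of replicates were 2.15 to 5.44 times what counting error alone would give (chi-square per degree of freedom). No pairing of libraries across groups by replicate number was seen. Residual profiles of libraries with the same number in different groups had correlations across genes from -0.0952 to 0.0603, and 0 of 30 such pairs exceeded 0.1. Pairs with different numbers ran from -0.0699 to 0.0976. This does not exclude that libraries with the same number shared a culture or batch.

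The comparisons, tests, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The comparisons were knockout against control, add-back against knockout, LY500307 against vehicle, and add-back against control. Vehicle against add-back cells is given among the additional observations only. Named genes were ESR2, then the 8 largest rises and 8 largest falls among called protein-coding genes. These had to have a mean log2 CPM of at least 1 and no overlap between the 3 libraries of each group. Up to 3 members with the smallest p were added for each list that passed its test, and always for the estrogen-responsive, cystatin, AP-1, epithelial and mesenchymal lists. Up to 5 genes called in all 3 main comparisons were added, and for the remaining comparisons the 3 largest changes in each direction. The rule named 1 further gene, which is not reported because its name was withheld from these texts, so a list can show fewer members than the rule gives. A fold against a group with 0 reads was computed against 3 counts summed over that group, which covers counting error only.

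Of 30 gene lists, 29 had at least 3 genes tested. Each was tested against all other genes with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over the 29 lists. Camera with an estimated correlation and fry were run beside it. Members called are counted over all genes tested and again adjusted over the list alone. Overlaps between lists of called genes were compared with the number that independent lists would share. Where comparisons shared libraries, 20 simulations of unchanged groups gave the overlap and covariance that the shared libraries alone produce. Otherwise a one-sided Fisher's exact test across genes was used, in which genes are not independent replicates.

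Alternatives were the Wald test of DESeq2 1.42.0, RLE and upper-quartile factors, limma-voom, no filter on low counts, a CPM of at least 1 in 3 libraries, the 6 libraries of a comparison alone, the replicate number as a block, and leaving out each library in turn. Offsets that remove a smooth trend of each library on GC content and transcript length were chosen after seeing the data. The edgeR test and the offsets were tested on simulated data with the depth of these libraries. At a true change of 1.5-fold the test called 59.6% of changed genes for knockout against control, 57.1% for add-back against knockout and 56% for LY500307 against vehicle. False calls were 2, 10 and 5. Few simulated genes changed, 47 of 19070 at 1.5-fold for knockout against control, where 46% of genes were called in the data. The adjusted p depends on how many genes change, so these percentages do not give the share of real changes found. With a simulated GC trend and no changed gene, 5299 of 19049 genes were called without offsets and 1 with them. The trend was smooth and no gene changed, so this cannot show whether the offsets also remove a real response related to GC content. Transcript counts were used for ESR2 only and no test was run on them.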

Results

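RNA was measured in KPL4 cells, a HER2-amplified human breast adenocarcinoma line, in 5 groups of 3 libraries: control cells with their own ERβ, ERβ knockout cells, add-back cells (knockout cells given ERβ again), and add-back cells treated with vehicle or with the ERβ agonist LY500307. Depth per library was 13649584 to 15932714 expected counts in control cells, 12614074 to 15891449 in knockout cells, 14966501 to 17736189 in add-back cells, 15046862 to 19390378 with vehicle and 16843036 to 18100010 with LY500307. The first principal component of log2 CPM held 38.0% of the variance and the second 21.4%. Control libraries, untreated knockout and add-back libraries, and vehicle and LY500307 libraries lay in 3 areas of this plane, and the groups that shared an area adjoined.

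**Figure D1:**
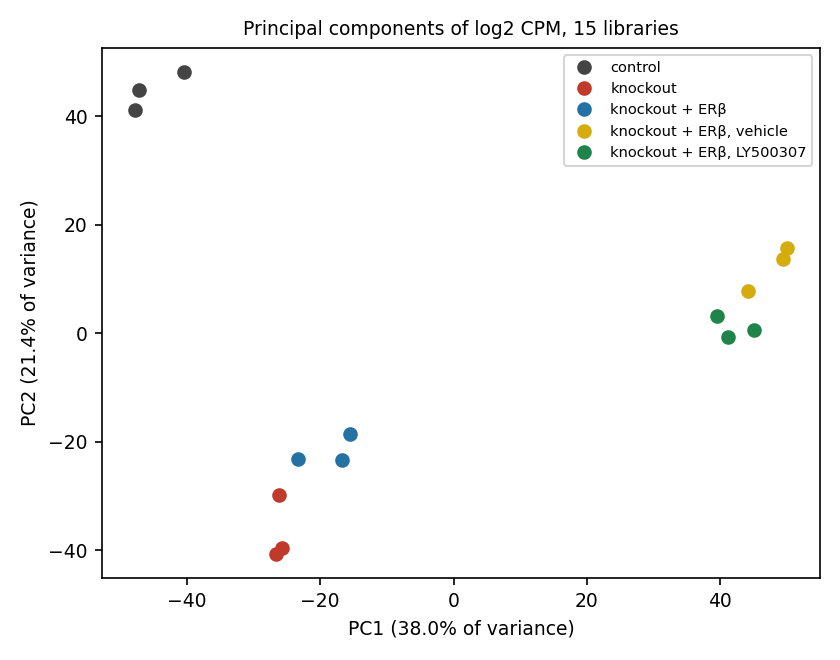
Principal components of log2 CPM over 19516 genes, with PC1 (38.0% of the variance) on the x axis and PC2 (21.4%) on the y axis; each point is 1 of 15 libraries, coloured by group. Control libraries lie apart from the rest, while knockout replicate 1 is nearer to add-back replicate 1 than to the other knockout libraries and vehicle replicate 3 nearer to LY500307 replicate 3 than to the other vehicle libraries.

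ESR2 (ENSG00000140009, GRCh38 chromosome 14, 64084232 to 64338112, minus strand), the gene of ERβ, was measured first. Its level was 5.76 ± 0.867 CPM in control cells and 4.41 ± 1.36 CPM in knockout cells (SD, n = 3 each), a log2 fold change of -0.38 ± 0.17 with an adjusted p of 0.0796. This difference did not pass the threshold, but the adjusted p was 0.0291 without a filter on low counts, 0.0344 without control replicate 2 and 0.00992 without knockout replicate 1. Under the other alternatives that gave a value the difference did not pass. An edit that ends the protein need not lower the mRNA, so the ESR2 level does not check the knockout label. Add-back cells had 32.8 ± 1.94 CPM, 7.40-fold more than knockout cells (adjusted p = 4.54e-12). ESR2 was at 45.2 ± 3.24 CPM with vehicle and 43.9 ± 1.36 CPM with LY500307 (log2 fold change -0.04 ± 0.08, adjusted p = 0.815). ESR2 overlaps SYNE2 on the opposite strand, which was expressed at 225 CPM on average, so reads shared with SYNE2 are part of the low ESR2 values if strand was not used in counting.

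**Figure D2:**
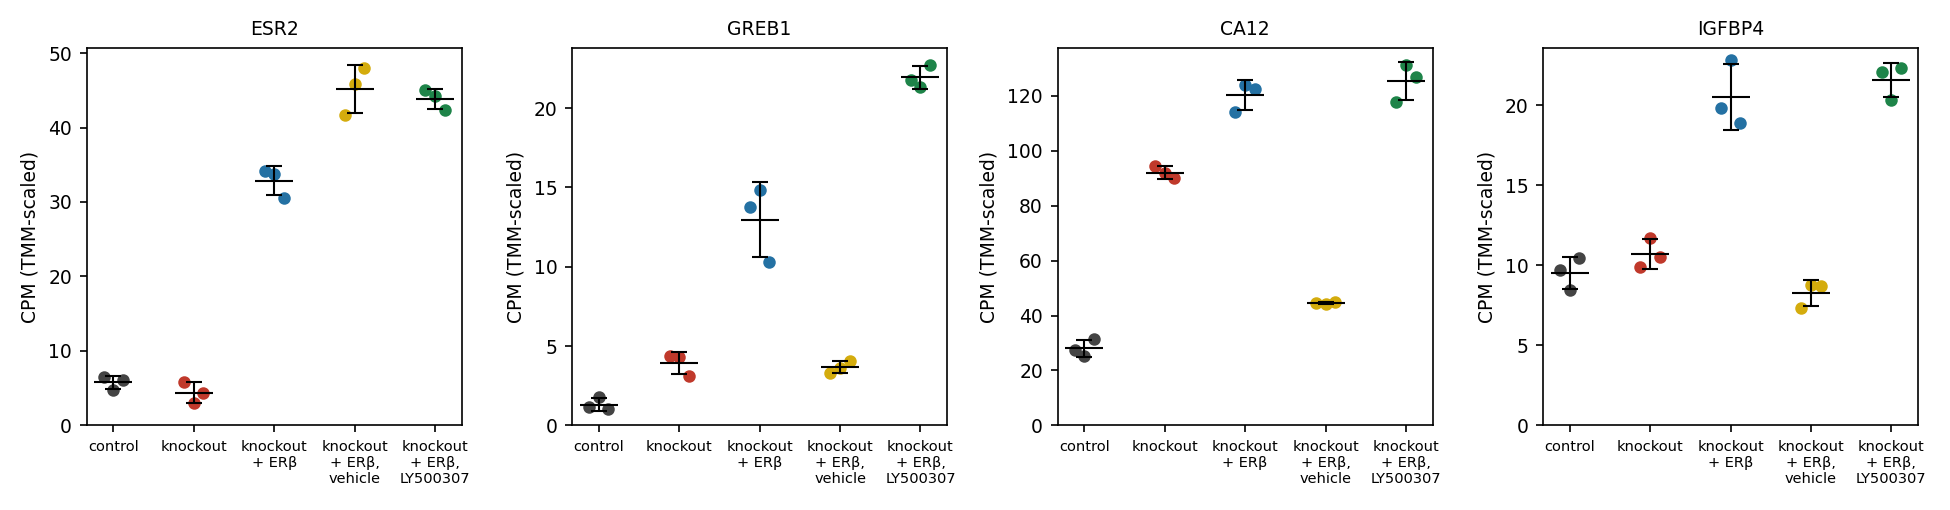
CPM of ESR2, GREB1, CA12 and IGFBP4 on linear y axes that start at 0, by group on the x axis; points are libraries, and bars are the mean and SD of 3 libraries. ESR2 is at 4.41 CPM in knockout and 32.8 CPM in add-back cells, and GREB1 is at 3.68 CPM with vehicle and 21.9 CPM with LY500307.

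Knockout against control asked what the loss of ERβ changed. CRISP3 (ENSG00000096006, chromosome 6, 49727384 to 49744437), which encodes a secreted cysteine-rich protein, rose 35.5-fold, from 7.50 ± 0.808 CPM in control cells to 266 ± 6.26 CPM in knockout cells (SD, n = 3 each). VTCN1, which encodes the immune checkpoint ligand B7-H4, rose from 0.470 ± 0.214 to 20.9 ± 1.59 CPM. ALDH1A1 (ENSG00000165092, chromosome 9, 72900662 to 73080442), a retinaldehyde dehydrogenase, fell 8.67-fold, from 1356 ± 64.2 to 156 ± 1.68 CPM. NRG1, a growth factor that binds ERBB3 and ERBB4, fell 17.1-fold, from 28.5 ± 1.96 to 1.67 ± 0.269 CPM. ERBB2 itself was at 3521 CPM in control and 5280 CPM in knockout cells (log2 fold change 0.58, adjusted p = 7.52e-12), and ESR1, the gene of ERα, at 10.0 and 17.4 CPM (log2 fold change 0.80, adjusted p = 2.96e-07). ERBB2 and ESR1 were chosen after their values were seen, and the list of HER2 amplicon and ERBB genes went both ways, with 9 of 19 higher and 6 lower (adjusted p = 0.843).

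Across all genes 8971 of 19516 were called in this comparison, 4561 higher and 4410 lower in knockout cells. With the GC content and length offsets 6868 of the 8971 were called again, and 40% of all calls were higher, against 50.8% without them. The following counts are without the offsets. Of the 8971 genes, 1146 were at least 2-fold higher and 467 at least 2-fold lower. GLYATL3 had 0 reads in the control libraries and 16.9 ± 0.439 CPM in knockout cells, at least 242-fold higher. KIRREL1, a cell adhesion gene, had 3 reads in control and 230 in knockout cells. PREX1 and ELMO1, regulators of the GTPase RAC, had log2 fold changes of 4.59 and 4.50, ADCY2, an adenylate cyclase, 4.58, and HSPB8, a small heat shock protein, 4.38. Among protein-coding genes with a mean log2 CPM of at least 1 and no overlap between groups, the rule for named genes, the others of the 8 largest falls were NRP2 (-3.57), a coreceptor of semaphorins and VEGF, FYB1 (-3.40), BMP5 (-3.16), ST8SIA4 (-2.93), DACH1 (-2.83) and TRIM31 (-2.77). NRP2 and DACH1 lie in stretches of chromosomes 2 and 13 where most genes were lower.

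Of 29 gene lists, 5 passed camera for knockout against control, and none of these calls held with an estimated correlation. Mitotic and G2/M genes fell, with 23 of 30 called lower and 2 higher (adjusted p = 8.02e-05; adjusted p = 0.421 with an estimated correlation), and the counts adjusted over the list alone were the same. ASPM, a spindle protein gene, changed by -0.67, CDK1, the mitotic kinase, by -0.89 and BUB1B, of the spindle checkpoint, by -0.41 on the log2 scale. Aryl hydrocarbon and xenobiotic response genes fell, with 11 of 17 lower and 3 higher, again the same adjusted over the list alone (adjusted p = 0.00227; adjusted p = 0.293 with an estimated correlation). The aldo-keto reductases AKR1B10 and AKR1C3 changed by -1.34 and -0.68, and the glucuronosyltransferase UGT1A6, which shares exons with its neighbours and lies in a stretch of chromosome 2 where most genes were lower, by -0.71. Replication-dependent histone genes rose, with 21 of 29 higher and 2 lower, or 22 and 2 adjusted over the list alone (adjusted p = 8.02e-05; adjusted p = 0.421 with an estimated correlation). H1-3, H4C1 and H2BC9 changed by 0.62, 0.79 and 0.77, and histone genes have near-identical copies that share reads. The histone list was kept as a sign of RNA composition.

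Other lists kept as signs of RNA and library composition moved in the same comparison. Ribosomal protein genes fell, with 37 of 48 lower and 2 higher, or 37 and 3 adjusted over the list alone (adjusted p = 5.64e-08; adjusted p = 0.293 with an estimated correlation), among them RPL37 (-0.53), RPL5 (-0.28) and RPS6 (-0.31). Mitochondrially encoded mRNAs fell, with 11 of 13 lower and 0 higher, or 13 and 0 adjusted over the list alone (adjusted p = 0.00239; adjusted p = 0.586 with an estimated correlation), among them MT-CO1 (-0.45), MT-CO2 (-0.75) and MT-CYB (-0.44). With offsets for GC content and length, chosen after seeing the data, the mitochondrial list did not pass (adjusted p = 0.102).

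The remaining 24 lists did not pass for knockout against control. Estrogen-responsive genes went both ways, with 10 of 21 higher and 5 lower, or 10 and 6 adjusted over the list alone (adjusted p = 0.0742). CA12, a carbonic anhydrase gene, rose from 28.1 ± 3.05 to 92.0 ± 2.27 CPM, NHERF1 changed by 0.71 and NRIP1, a nuclear receptor corepressor, by -0.77. AP-1 and immediate-early genes had 12 of 23 higher and 6 lower, or 13 and 6 adjusted over the list alone (adjusted p = 0.0924), with IER3 at 1.87, DUSP6, a phosphatase of ERK, at 1.85 and MYC at -0.61. Epithelial genes had 16 of 29 higher and 8 lower, the same adjusted over the list alone (adjusted p = 0.104), with keratins KRT19 at 1.04 and KRT18 at -0.49 and the desmosomal DSP at -0.43. With the offsets this list pointed down, with 9 higher and 13 lower (adjusted p = 0.929). Mesenchymal genes had 6 of 15 higher and 1 lower, or 6 and 2 adjusted over the list alone (adjusted p = 0.0538), with TNC, the matrix protein tenascin C, at 5.01, COL6A1 at 1.68 and COL6A2 at 2.90. Markers of immune, endothelial and stromal cells had 2 of 7 higher and 0 lower (adjusted p = 0.735), with a negative median and a positive mean. Among cystatins only CST3 and CST6 were measured, too few for a list test, and CST3 was higher in knockout cells (log2 fold change 0.30, adjusted p = 0.000531).

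Log2 fold changes were not spread evenly along the genome. Running medians of neighbouring genes had an SD of 0.199, against at most 0.0702 in 20 shuffled gene orders. The stretches below were picked by their running medians, so their own medians and counts are large by selection. On chromosome 13 from 32400723 to 114337626, 181 of 245 genes were lower and 7 higher in knockout cells, with a median log2 fold change of -0.84. On chromosome 2 from 177392644 to 219178106, 142 of 207 genes were lower and 11 higher (median -0.58), and from 219219380 to 240617705, 86 of 128 were lower and 9 higher (median -0.54). At the end of chromosome 14, from 103331674 to 105979146, 38 of 53 genes were higher and 0 lower (median 0.82). These stretches stood out among 11 in their running medians, and with offsets for GC content and length their medians were -0.79, -0.52, -0.56 and 0.42. The other 7, on chromosomes 9, 11, 16, 19, 20 and 22, had medians of 0.43 to 0.66, which fell to between -0.02 and 0.06 with the offsets. In add-back against knockout cells the stretches of chromosomes 13, 2 and 14 had medians of 0.11, 0.06, 0.02 and -0.21.

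**Figure D3:**
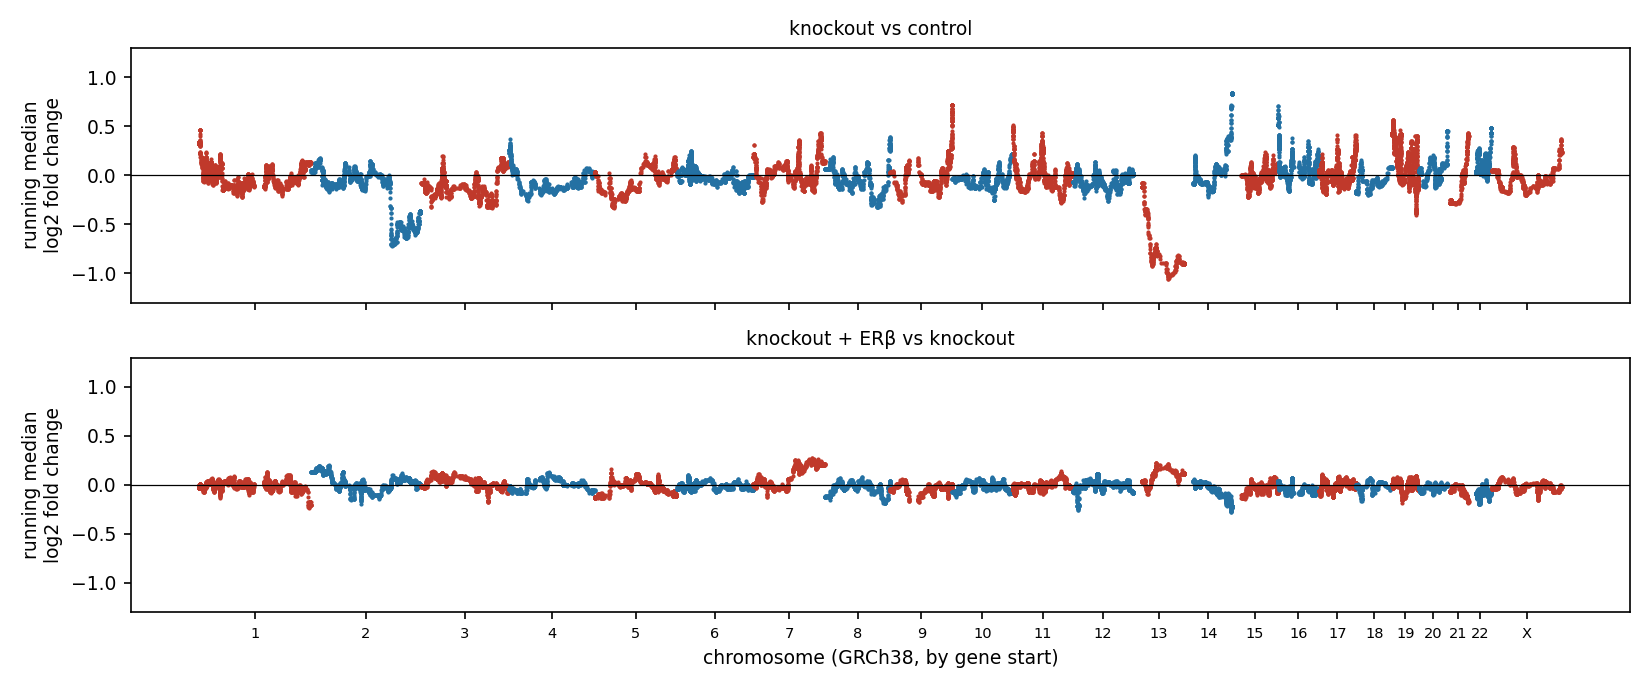
Running median of the log2 fold change over windows of 51 neighbouring genes (y axis) by gene start along GRCh38 chromosomes 1 to 22 and X (x axis), for knockout against control (upper panel) and add-back against knockout cells (lower panel). In knockout against control the genes of chromosome 13 have a median of -0.75, and in add-back against knockout 0.08.

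**Figure D4:**
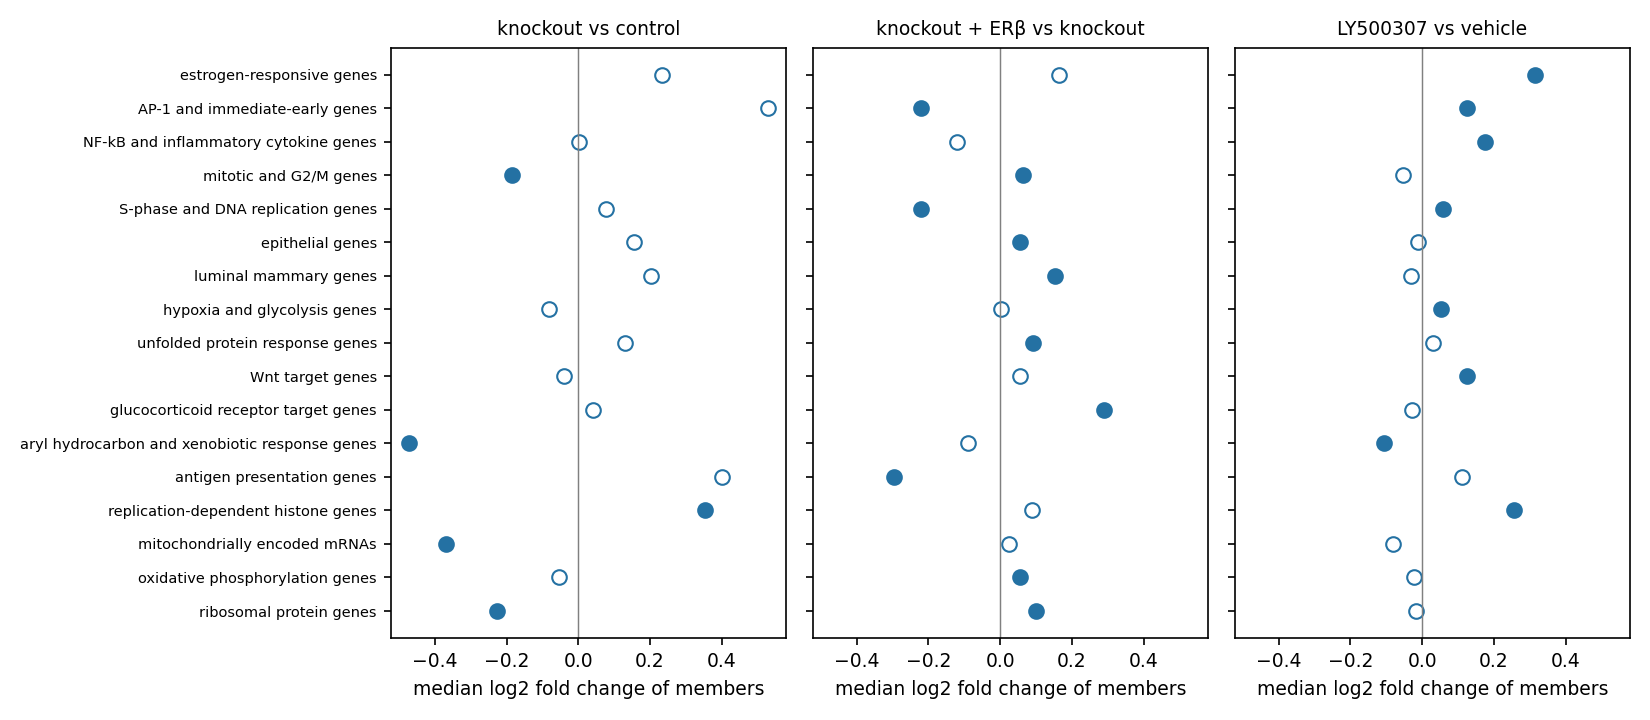
Median log2 fold change of the members of each gene list (x axis, the same scale in all 3 panels) for the lists (y axis) that passed camera in at least 1 of the 3 comparisons; filled points passed at an adjusted p under 0.05 with the preset correlation and open points did not. Estrogen-responsive genes have a median of 0.31 for LY500307 against vehicle.

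Add-back against knockout asked what the return of ERβ changed. CRISP3 fell from 266 ± 6.26 CPM in knockout to 39.9 ± 0.550 CPM in add-back cells (SD, n = 3 each), KLK5 (ENSG00000167754), a secreted serine protease gene, from 20.9 ± 0.968 to 1.5 ± 0.0987 CPM, and MME, the cell-surface peptidase neprilysin, from 52.8 ± 0.6 to 14.03 ± 1.17 CPM. PTPRR, a tyrosine phosphatase gene, rose from 1.67 ± 0.207 to 13.3 ± 0.783 CPM, and SOX2, a transcription factor gene, from 1.45 ± 0.128 to 6.18 ± 0.490 CPM. The estrogen-responsive gene GREB1 rose 3.34-fold, from 3.94 ± 0.704 to 12.98 ± 2.39 CPM. It was at 1.31 ± 0.416 CPM in control cells, so this rise led away from the control level.

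In this comparison 3824 of 19516 genes were called, 2030 higher and 1794 lower in add-back cells, with 157 at least 2-fold higher and 307 at least 2-fold lower. The balance between directions depended on scaling: 53.1% of calls were higher with TMM factors, 42% with upper-quartile factors and 64.2% with DESeq2. Under the rule for named genes the other largest rises were ST8SIA4 (log2 fold change 2.51), TRIM31 (2.28), SYTL5 (2.16), MAOA (2.00), a monoamine oxidase, and FOXC1 (1.97), a transcription factor. Under it the other largest falls were GLYATL3 (-4.68), ELMO1 (-2.41), NCAM1 (-2.39), a cell adhesion gene, PGM5 (-2.08) and VTCN1 (-2.02).

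For add-back against knockout, 10 of 29 lists passed, and none of these calls held with an estimated correlation. S-phase and DNA replication genes fell, with 21 of 32 lower and 0 higher, or 23 and 0 adjusted over the list alone (adjusted p = 2.33e-10; adjusted p = 0.165 with an estimated correlation). The helicase genes MCM3 and MCM6 changed by -0.54 and -0.30 and E2F1, a cell cycle transcription factor, by -0.49. Mitotic and G2/M genes moved the other way, with 10 of 30 higher and 3 lower, or 11 and 3 adjusted over the list alone (adjusted p = 0.0242; adjusted p = 0.56 with an estimated correlation), among them TOP2A (0.25), HMMR (0.40) and CENPA (0.38). Antigen presentation genes fell, with 8 of 20 lower and 0 higher, or 9 and 2 adjusted over the list alone (adjusted p = 0.000474; adjusted p = 0.187 with an estimated correlation). The peptide transporter TAP1 changed by -0.58, the transcription factor IRF1 by -0.56 and HLA-DRA by -3.47, from 1.44 CPM to 0.119 CPM. AP-1 and immediate-early genes fell, with 8 of 23 lower and 0 higher, or 9 and 2 adjusted over the list alone (adjusted p = 0.0406; adjusted p = 0.411 with an estimated correlation), among them CCN1 (-0.41), CCN2 (-1.67) and ATF3 (-0.71).

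Luminal mammary genes rose in add-back cells, with 8 of 20 higher and 1 lower, or 10 and 1 adjusted over the list alone (adjusted p = 0.00221; adjusted p = 0.204 with an estimated correlation), among them KRT8 (0.52), KRT18 (0.37) and AGR2 (0.32). Epithelial genes rose, with 10 of 29 higher and 2 lower, the same adjusted over the list alone (adjusted p = 0.0309; adjusted p = 0.426 with an estimated correlation), among them DSP (0.36) and the same keratins. Unfolded protein response genes rose, with 12 of 27 higher and 2 lower, or 12 and 3 adjusted over the list alone (adjusted p = 0.00609; adjusted p = 0.56 with an estimated correlation). PDIA4 and PDIA6, protein disulfide isomerases, changed by 0.57 and 0.33 and ASNS, the asparagine synthetase, by 0.54. Glucocorticoid receptor targets rose, with 7 of 17 higher and 1 lower, or 9 and 2 adjusted over the list alone (adjusted p = 0.0309; adjusted p = 0.411 with an estimated correlation), among them MAOA, FKBP5 (0.36) and BCL6 (0.29). Nuclear genes of oxidative phosphorylation rose, with 6 of 31 higher and 0 lower, the same adjusted over the list alone (adjusted p = 0.0309; adjusted p = 0.56 with an estimated correlation), among them NDUFS1 (0.22), SDHB (0.17) and COX6A1 (0.18). Ribosomal protein genes, a sign of library composition, rose too, with 22 of 48 higher and 0 lower, or 27 and 0 adjusted over the list alone (adjusted p = 1.98e-07; adjusted p = 0.204 with an estimated correlation), among them RPS2 (0.24), RPL15 (0.31) and RPL30 (0.25).

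Estrogen-responsive genes had 8 of 21 higher and 2 lower in add-back cells, or 9 and 2 adjusted over the list alone, and the list did not pass (adjusted p = 0.0698). Beside GREB1, IGFBP4, which encodes a binding protein of insulin-like growth factors, rose from 10.7 to 20.5 CPM and the trefoil factor TFF1 from 0.263 to 2.31 CPM. Mesenchymal genes had 3 of 15 higher and 3 lower, the same adjusted over the list alone (adjusted p = 0.642), with a median of 0.06, a mean of -0.31 and a test that pointed down. Among them FN1, fibronectin, fell from 249 ± 11 to 116 ± 3.03 CPM, TNC from 3.26 to 0.205 CPM and COL5A1 changed by -1.17. The cystatin gene CST6 changed by -1.18 at a low level (1.14 CPM in knockout and 0.511 CPM in add-back cells, adjusted p = 0.0337).

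Whether the return of ERβ undid the knockout differences was asked next. Of the 8971 genes called in knockout against control, 2185 (24.4%) were called the opposite way in add-back against knockout and 480 the same way. CRISP3, VTCN1, ELMO1 and TNC were higher in knockout cells and then fell, while ST8SIA4, TRIM31 and SYTL5 were lower and then rose. Genes higher in knockout and then lower numbered 1007 against 419.3 for independent lists, and genes lower and then higher 1178 against 458.7. The same knockout libraries enter both comparisons, which by itself gives opposite signs. Simulated unchanged groups had a covariance of -0.0372 across genes against a measured -0.145. Their correlation was -0.51 against a measured -0.448. A correlation is scaled by the spread of the fold changes, which was wider in the data than in unchanged groups. The correlations are therefore on unlike scales and decide nothing. Simulated groups had at most 1 shared call, but hardly any gene is called in unchanged groups, so this count tests nothing. The cause of the reversal was not tested. Of the 2185 genes, 1081 no longer differed detectably from control, 957 were still called on the knockout side and 147 on the other side of control.

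Add-back against control showed which differences were left. HSPB8 was at 4.30 CPM in add-back and 0.0954 CPM in control cells, and KIRREL1 at 3.69 and 0.0743 CPM. GLYATL3 was at 0.649 CPM, at least 9.33-fold higher than its 0 reads in control cells. BMP5 (-2.97), NRG1 (-2.37) and NRP2 (-2.13) were the largest falls under that rule. In all 8942 of 19516 genes were called, 4518 higher and 4424 lower. Of the knockout calls 6536 (72.9%) were called in the same direction in add-back against control, 3387 higher and 3149 lower, against 1055.9 and 999.7 for independent lists. The same control libraries enter both comparisons. Simulated unchanged groups had a covariance of 0.0376 across genes against a measured 0.388, and a correlation, on unlike scales as above, of 0.515 against a measured 0.802. They shared 0 calls, but hardly any gene is called in unchanged groups, so this count tests nothing.

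For add-back against control 12 of 29 lists passed camera, and none of these calls held with an estimated correlation (lowest adjusted p = 0.146). Luminal mammary genes were higher, with 15 of 20 higher and 2 lower (adjusted p = 1.11e-05), as were estrogen-responsive genes, with 12 of 21 higher and 3 lower (adjusted p = 0.00202), and unfolded protein response genes, with 17 of 27 higher and 4 lower (adjusted p = 0.00365). Histone genes, kept as a sign of RNA composition, had 22 of 29 higher and 2 lower (adjusted p = 8.31e-06). Aryl hydrocarbon and xenobiotic response genes had 12 of 17 lower and 4 higher (adjusted p = 0.00176), and S-phase and DNA replication genes 19 of 32 lower and 5 higher (adjusted p = 0.00569). These 6 lists passed again with the offsets. The mitotic, epithelial, mesenchymal, TGF-beta, mitochondrial and ribosomal protein lists passed too, but did not with the offsets (adjusted p = 0.138, 0.348, 0.11, 0.174, 0.141 and 0.0973).

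LY500307 against vehicle asked which genes responded to the agonist in add-back cells. GREB1 (ENSG00000196208, chromosome 2, 11482341 to 11642788), an estrogen-induced gene, rose 5.96-fold, from 3.68 ± 0.381 CPM with vehicle to 21.9 ± 0.710 CPM with LY500307 (SD, n = 3 each). CA12 (ENSG00000074410, chromosome 15, 63321378 to 63382161) rose 2.81-fold, from 44.5 ± 0.331 to 125 ± 6.84 CPM. IGFBP4 (ENSG00000141753, chromosome 17, 40443461 to 40457731) rose 2.60-fold, from 8.26 ± 0.822 to 21.6 ± 1.06 CPM. CISH, a feedback inhibitor of cytokine signalling, rose from 1.39 ± 0.141 to 5.22 ± 0.850 CPM (it overlaps MAPKAPK3 on the opposite strand, at 57 CPM on average), and CCNG2, an atypical cyclin gene, fell from 78.8 ± 5.63 to 58.1 ± 2.22 CPM (adjusted p = 5.42e-05).

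Estrogen-responsive genes rose as a group with LY500307, with 11 of 21 higher and 0 lower, or 12 and 0 adjusted over the list alone. This list passed camera (adjusted p = 9.16e-11) and was the only 1 of 8 passing lists that held with an estimated correlation (adjusted p = 0.00566). With offsets for GC content and length it passed again (adjusted p = 2.74e-13), with 8 higher and 0 lower. TFF1, chosen after its values were seen, was at 0.567 CPM with vehicle and 4.04 CPM with LY500307 (log2 fold change 2.80, adjusted p = 4.65e-06).

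In all 1389 of 19516 genes were called for LY500307 against vehicle, 931 higher and 458 lower, and 28 were at least 2-fold higher and 8 at least 2-fold lower. Under the rule for named genes, which leaves out genes at low levels, the other largest rises were A4GALT (log2 fold change 1.252), ZNF628 (1.14), DOK7 (1.04) and the histone gene H3C13 (1.00). The other largest falls under it were MUC19 (-0.52), S100A4 (-0.48), IL1RL1 (-0.44), OTULINL (-0.43), DNM3 (-0.42), TMEM45B (-0.41) and KLK10 (-0.40). All of these falls, and the rises of ZNF628 and H3C13, lost their calls under at least 1 alternative. With the GC content and length offsets 276 genes were called, 190 higher and 86 lower, of which 238 were among the 1389. The number called was 403 without vehicle replicate 1, 299 without vehicle replicate 2, 586 without LY500307 replicate 1 and 487 without LY500307 replicate 2. Of the 43 named genes called here, 19 kept their call under every alternative that gave a value, among them GREB1, CA12, IGFBP4, CISH, A4GALT, DOK7, CCNG2, MYC, BIRC3, TNFAIP2, UHRF1, PFKFB3 and KRT19.

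The other 7 lists that passed had smaller changes. Among their named genes CXCL8 and CCND1, like others given below, lost their calls under at least 1 alternative. NF-kB and inflammatory cytokine genes rose, with 3 of 15 higher and 0 lower, or 6 and 0 adjusted over the list alone (adjusted p = 0.000242; adjusted p = 0.187 with an estimated correlation), namely BIRC3 (0.55), TNFAIP2 (0.67) and CXCL8 (0.49). Hypoxia and glycolysis genes rose, with 4 of 29 higher and 0 lower, or 6 and 1 adjusted over the list alone (adjusted p = 0.0179; adjusted p = 0.214 with an estimated correlation), among them the glycolytic regulator PFKFB3 (0.65), ALDOA (0.17) and VEGFA (0.14). With the offsets 1 was higher and 0 lower and the list still passed (adjusted p = 0.0164), while ALDOA and VEGFA lost their calls under at least 1 alternative. S-phase and DNA replication genes rose, with 7 of 32 higher and 0 lower, or 8 and 0 adjusted over the list alone (adjusted p = 0.000426; adjusted p = 0.214 with an estimated correlation), among them MCM2 (0.24), UHRF1 (0.25) and TK1 (0.29). With the offsets 2 were higher and the list still passed (adjusted p = 1.12e-06), and MCM2 and TK1 lost their calls under at least 1 alternative. AP-1 and immediate-early genes rose, with 3 of 23 higher and 0 lower, the same adjusted over the list alone (adjusted p = 0.0213; adjusted p = 0.212 with an estimated correlation), namely MYC (0.33), CCN1 (0.29) and JUND (0.40). The offsets ended this list's call (adjusted p = 0.193) and moved JUND to -0.03. Wnt targets rose, with 2 of 17 higher and 1 lower, or 3 and 1 adjusted over the list alone (adjusted p = 0.0417; adjusted p = 0.187 with an estimated correlation): MYC and CCND1 (0.13) were higher and TNFRSF19 (-0.64) lower.

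Aryl hydrocarbon and xenobiotic response genes fell with LY500307, with 6 of 17 lower and 1 higher, or 10 and 1 adjusted over the list alone (adjusted p = 0.00375; adjusted p = 0.187 with an estimated correlation). GCLM, of glutathione synthesis, changed by -0.22 and AKR1B10 by -0.19, and the offsets ended their calls (adjusted p = 0.0876 and 0.152). With the offsets 1 gene of this list was lower and 0 higher, and the list still passed (adjusted p = 0.000629). Replication-dependent histone genes rose, with 13 of 29 higher and 0 lower, or 16 and 0 adjusted over the list alone (adjusted p = 4.47e-10; adjusted p = 0.187 with an estimated correlation), among them H1-5 (0.25), H2AC13 (0.28) and H3C7 (0.49). With the offsets 5 histone genes were higher and the list still passed (adjusted p = 2e-05), while none of the 3 named histone genes was called. The histone list was kept as a sign of RNA composition. Epithelial genes had 7 of 29 higher and 0 lower, or 10 and 5 adjusted over the list alone (adjusted p = 0.125), with a negative median, a mean of 0.08 and a test that pointed up. With the offsets the test pointed down, with 1 higher and 1 lower (adjusted p = 0.309). KRT19 changed by 0.38, ST14 by 0.25 and KRT7 by 0.22, and the offsets left KRT7 at 0. Mesenchymal genes had 0 of 15 higher and 1 lower, COL5A2 at -0.31, or 2 and 1 adjusted over the list alone. Their median was 0.26 and their test pointed up without passing (adjusted p = 0.0798).

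Genes that moved with the receptor were then compared with those that moved with its agonist, in libraries that the comparisons do not share. GREB1, CA12, IGFBP4, SYTL5 and SCNN1A were higher in both add-back against knockout and LY500307 against vehicle. Genes higher in both numbered 113 against 96.8 for independent lists (one-sided Fisher's exact test across genes, p = 0.0447), and genes lower in both 65 against 42.1 (p = 0.000279). Genes higher with ERβ and lower with LY500307 numbered 138 against 47.6 (p = 3.62e-32), and the reverse 84 against 85.6 (p = 0.59, the same exact test). With the offsets the same exact test gave for these pairs of directions 59 against 28 (p = 7.51e-09), 19 against 7.09 (p = 5.96e-05), 29 against 12.7 (p = 7.95e-06) and 32 against 15.7 (p = 8.19e-05). Same-way and opposite-way pairs were both in excess, so these overlaps do not show that receptor and agonist moved genes in the same direction. Genes moved in the same direction numbered 178 in all, 70 without vehicle replicate 1, 57 without vehicle replicate 2, 89 without LY500307 replicate 1 and 80 without LY500307 replicate 2.

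In all, 325 genes were called in each of the 3 main comparisons, and 75 of them moved against their knockout change with both the receptor and the agonist. No expected number was computed for the 75, so they are not shown to be an excess. SYTL5 changed by -1.39 in knockout, 2.16 in add-back and 0.99 with LY500307. SCNN1A, a subunit of the epithelial sodium channel, changed by -0.51, 0.50 and 0.31, and SLC40A1, the iron exporter ferroportin, by 0.45, -0.59 and -0.34. MAB21L4 changed by 0.79, -0.83 and 0.96, and CA12 by 1.71, 0.39 and 1.49. Over all genes called in both knockout against control and LY500307 against vehicle, 861 moved the same way and 214 opposite ways. For independent lists 217.6 would be higher in both, where 668 were (one-sided Fisher's exact test across genes, p = 3.34e-227), and 103.5 lower in both, where 193 were (p = 3.38e-21). Genes higher in knockout and lower with LY500307 numbered 143 against 107 (p = 6.05e-05), and the reverse 71 against 210.4 (p = 1, the same exact test). With the offsets the excess of same-way genes was smaller: the same exact test gave for these pairs of directions 82 against 32.2 (p = 1.63e-17), 37 against 21.9 (p = 0.000275), 32 against 14.6 (p = 5.37e-06) and 52 against 48.3 (p = 0.293).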

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

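The tests on ERα, on the return of the receptor, on shared shifts of all genes, on changes of at least 2-fold and with GC content offsets were chosen after the results were seen.

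ESR2 transcripts appeared in the transcript table, which the gene comparisons do not use, at levels above control and knockout cells. ESR2-201 had a mean of 95.3 expected counts in add-back libraries and 0 in control and knockout libraries. ESR2-206 had 271 expected counts in add-back, 1.41 in control and 1.33 in knockout libraries. ESR2-210 had 54.7 expected counts in add-back libraries and 0 in control and knockout libraries. ESR2-202 had 30.3, 26.9 and 38.5 expected counts in control, knockout and add-back libraries.

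Most knockout differences stayed after ERβ was put back: 72.9% of the knockout calls were called the same way in add-back against control. Knockout libraries had GC slopes of 0.0771, 0.14 and 0.155 log2 units per 10 points of GC content. Add-back libraries had 0.13, 0.146 and 0.106, and control libraries -0.136, -0.073 and -0.121. With offsets that remove this trend, 2268 genes were higher and 3356 lower in both groups against control. Independent lists would share 632 and 1120. Library scaling as the whole account is argued against by direction. A scaling error moves all genes the same way, and the persisting genes went both ways, 3387 higher and 3149 lower. At least 74.4% of them stayed called, in either direction, after any shared shift of all genes from -1 to 1 on the log2 scale. That share follows from this division and adds no test. Such a shift changes how calls divide between directions. The 98.7% that kept call and sign under RLE and upper-quartile factors test little, since these factors hardly moved the median of all genes. Blocks of genes along chromosomes 2 and 13 were lower, and subtracting the running median of neighbouring genes left 78.4% of the persisting genes called, so copy-number changes between the cell lines remain open for part of them. Among persisting changes of at least 2-fold 93.7% stayed called. This follows largely from their size, since the running medians had an SD of 0.199 and 19.1% of genes lay in windows beyond 0.2. It shows that these changes exceeded those of neighbouring genes and does not decide their cause. The 72.9% is the pattern itself and tests no cause, so loss of the receptor stays open beside differences between lines that arose during cloning, changes that do not reverse and an add-back level of ESR2 above that of control cells, none of which was tested.

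More genes were higher than lower with LY500307 (67% of calls). Scaling stays open: at least 63% of calls were higher under RLE and upper-quartile factors, but these left the median of all genes at -0.018 and -0.022, against -0.018, and so tested little. A GC content or gene length bias stays open and cannot be told apart from a response: called higher genes had a median GC content of 61.1%, called lower genes 41%, and removing a trend on both left 59.8% of calls higher, between the bounds set for either outcome. The GC slope of the vehicle libraries was -0.148, -0.166 and -0.0738 log2 units per 10 points of GC content, and that of the LY500307 libraries 0.00566, 0.00363 and -0.0456, so many of the calls may follow this trend: offsets that remove it left 276 calls, 68.8% of them higher.

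Estrogen-responsive genes rose with LY500307 under the trend offsets as well. A candidate explanation beside ERβ is action of the agonist through ERα: ESR1 was at 10.7 CPM in the vehicle libraries (mean), so it was not absent. No knockout cells were treated with LY500307, and the explanations cannot be told apart in this design.

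Each comparison of 6 libraries can be split in 10 ways, too few for a share under 0.05. In fits of the 6 libraries alone, the real split gave 8269 calls for knockout against control (highest other split 1), 3642 for add-back against knockout (0), 1416 for LY500307 against vehicle (0), 8517 for add-back against control (0) and 8928 for vehicle against add-back (0). In each case 1 of 10 splits, the real one, gave as many. Every other split mixes the groups, so a large group difference widens the spread on each side and few calls result by construction.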

How the results depend on the processing

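Offsets for GC content and length were chosen after the data were seen; all other alternatives were planned. All 47 named genes called in knockout against control and all 53 in add-back against knockout kept call and direction under every alternative that gave a value, and 19 of 43 did so for LY500307 against vehicle. Counts of calls stayed within 1.5 times under RLE, upper-quartile, limma-voom, the stricter filter, the 6 libraries alone and the replicate block. The cause was not tested for the following, except where named. DESeq2 gave 1085 genes lower in add-back against knockout, and no filter gave 1593 higher with LY500307. A 2-fold minimum in both comparisons, which by construction keeps fewer genes, left 270 reversed genes and 3 shared with the agonist. The offsets gave 276 calls with LY500307, 190 higher and 86 lower, and 78 shared with the receptor. Among the genes reported they turned JUND to -0.03 and KRT7 to 0. They left 40% of knockout calls higher, against 50.8%. An estimated correlation left 0, 0 and 1 lists passing for knockout, add-back and LY500307, and fry, which compares a list with no other genes, 25, 17 and 13.

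Leaving out 1 library lowers the number of libraries behind each fit. Knockout against control then gave 7946 to 8491 calls (4080 to 4414 higher, 3866 to 4227 lower), add-back against control 7826 to 8401 (4173 to 4511, 3593 to 3992), add-back against knockout 2918 to 3596 (1705 to 2144, 1213 to 1452) and vehicle against add-back 8018 to 8934 (4142 to 4506, 3876 to 4428). Reversed genes numbered 1793 to 2245. LY500307 against vehicle gave 299 (without vehicle replicate 2) to 1844 calls (without vehicle replicate 3), 240 to 1378 higher and 59 to 466 lower, and 57 to 262 shared with the receptor. It gave 403 calls without vehicle replicate 1, 586 and 487 without LY500307 replicates 1 and 2, and 243 lower without LY500307 replicate 3. The log2 fold change of ESR2 with LY500307 ran from -0.085 (without vehicle replicate 1) to 0.019 (without vehicle replicate 3). In simulations at these depths with 3 libraries per group, 39.6%, 34% and 26.5% of genes with the smallest simulated change were called, and neither depth nor the number of libraries was varied. Few genes changed in these simulations, so the percentages do not carry over to the comparisons of the data.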

Other observations

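Vehicle-treated add-back cells were kept in depleted medium and given DMSO, while the labels do not state the medium of untreated add-back cells, so which of these differed is not known. Between them 9381 of 19516 genes were called, 5160 higher and 4221 lower. The balance between directions depended on the processing, with 55% of calls higher under TMM factors. It was 48.1% with upper-quartile factors and 48.3% with offsets for GC content and length. CYP1A1, a cytochrome induced through the aryl hydrocarbon receptor, rose from 0.927 ± 0.305 to 36.7 ± 3.74 CPM (SD, n = 3 each), IL1RL1, the receptor of interleukin 33, from 1.20 ± 0.252 to 29.4 ± 3.44 CPM and GLYATL3 from 0.649 ± 0.0613 to 18.3 ± 3.96 CPM. ATOH8, a transcription factor, fell from 25.9 ± 0.454 to 0.222 ± 0.0388 CPM, ID3, a target of BMP signalling, from 129 ± 2.02 to 7.30 ± 0.417 CPM and EPS8L3 from 5.23 to 0.138 CPM. Cholesterol biosynthesis genes rose, with 21 of 25 higher and 0 lower, the same adjusted over the list alone (adjusted p = 3.26e-08; adjusted p = 0.0274 with an estimated correlation). Basal and myoepithelial genes rose, with 10 of 15 higher and 2 lower, or 12 and 2 adjusted over the list alone (adjusted p = 0.000577; adjusted p = 0.0308 with an estimated correlation).

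Of 13 lists that passed, 2 held with an estimated correlation. Calls that were lost included those of interferon-stimulated genes (24 of 34 higher, 4 lower; adjusted p = 1.88e-05; adjusted p = 0.117 with an estimated correlation), NF-kB genes (11 of 15 higher, 1 lower; adjusted p = 8.81e-05; adjusted p = 0.117) and antigen presentation genes (14 of 20 higher, 0 lower; adjusted p = 0.00277; adjusted p = 0.117). TGF-beta targets had 13 of 23 lower and 5 higher (adjusted p = 0.0134; adjusted p = 0.149 with an estimated correlation), Wnt targets 10 of 17 lower and 2 higher (adjusted p = 0.0147; adjusted p = 0.117) and glucocorticoid receptor targets 11 of 17 lower and 4 higher (adjusted p = 0.0134; adjusted p = 0.168). Genes of fatty acid and lipid synthesis had 12 of 21 higher and 5 lower (adjusted p = 0.0134; adjusted p = 0.149 with an estimated correlation). The lists kept as signs of RNA and library composition moved too: histone genes had 21 of 29 lower and 3 higher (adjusted p = 0.000112; adjusted p = 0.315 with an estimated correlation), ribosomal protein genes 28 of 48 higher and 6 lower (adjusted p = 0.0134; adjusted p = 0.42) and noncoding RNAs 8 of 15 lower and 1 higher (adjusted p = 0.0192; adjusted p = 0.117). With offsets for GC content and length, chosen after seeing the data, the histone and noncoding RNA lists did not pass (adjusted p = 0.197 and 0.799). Estrogen-responsive genes had 8 of 21 higher and 11 lower and did not pass (adjusted p = 0.245), with GREB1 at -1.82, CA12 at -1.43, IGFBP4 at -1.31 and TFF1 at -1.99. These genes, named in other comparisons, were not picked by the rule here, and all were on the falling side of a list that went both ways. ESR1 changed by -0.68 (adjusted p = 1.29e-06). Markers of immune, endothelial and stromal cells had 6 of 7 higher and 1 lower (adjusted p = 0.00541; adjusted p = 0.0761 with an estimated correlation), among them KDR, from 14.1 to 41.9 CPM, VWF, from 2.81 to 8.74 CPM, and CD68, from 0.709 to 6.10 CPM.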
